A study of Homo sapiens with 8 samples.

How the data were processed

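RNA levels were measured in P493-6 cells, a human B cell line with a tetracycline-regulated MYC gene that tetracycline switches off. Per the labels, total RNA of each sample was labelled with a single dye, with RNA spike-ins added at labelling, and hybridised to 1-channel Agilent arrays that hold probes for mRNAs and long noncoding RNAs (lncRNAs). There were 8 arrays in 4 groups of 2: untreated cells (Myc on), cells kept with 0.1 µg/ml tetracycline for 72 h (repressed), and cells moved to tetracycline-free medium after such a repression and collected 4 h or 24 h later (re-induced). These times after removal are read from the treatment protocol, while the descriptions of the samples say 4 h and 24 h after tetracycline treatment. The 8 arrays sat on 1 slide and were read in 1 scan, each group in a slide column of its own and each replicate number in a slide row of its own, so slide column and group cannot be told apart. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples. Presence of tetracycline and Myc level were confounded in the repressed cells, and re-induced cells were spun down and given fresh medium, which the labels do not describe for untreated cells. Against repressed cells, the return of Myc came together with removal of tetracycline and this change of medium.

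Per the file headers, the deposited spot signals are intensity values on a linear scale, background-subtracted and adjusted by the error model of Feature Extraction 10.7.3.1, with no scaling between arrays. Raw median signals of the spot and of its local background were deposited as intensity in the same files, with the scanner software's flags for signal well above background, saturation and outliers. The authors also deposited a table of log2 values in which the 8 columns hold 1 shared set of values with a median of 3.88, as quantile normalization gives. The labels do not state how that table was made, so it served only as an alternative. Each array has 62976 spots, of which 1319 are controls and 61657 are for RNA. These spots hold 58642 distinct probes, 30109 of them from the maker's catalogue and 28533 custom probes for which the files give no gene. Of the catalogue probes 8320 carry an accession or name of their own, and 8124 were matched to 7413 gene symbols through the RefSeq gene table. The other 21985 catalogue probes have no gene name in the files, so that 50518 probes in all have none, and 106 RefSeq mRNA accessions were not matched. No genome position is given for any gene, since the files and the reference table differ in genome build. Probes for XIST and for genes on the Y chromosome (13) were dropped. Saturated spots numbered 0, and 852 outlier spots over all arrays were left out, which left 150 probes with a missing value on some array.

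The log2 of the processed signal was taken, each array was scaled by subtracting the 75th percentile of its RNA spots, and the spots of a probe were averaged. Probes were kept when well above background on both arrays of at least 1 group. A gene's value is that of its probe with the highest mean log2 signal, and probes without a gene stayed as features of their own. This left 30777 features, of which 5323 were named genes (5306 coding genes, 6 lncRNAs by RefSeq gene type and 11 others), 14574 were catalogue probes without a gene and 10880 were custom probes. One group-means model over all 8 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 4 residual and 1.80 prior degrees of freedom). Each comparison was tested two-sided by limma, with Benjamini-Hochberg adjustment over all 30777 features and a threshold of 0.05. "Rose" and "fell" refer to adjusted p-values under that threshold. The comparisons were repressed minus untreated, 4 h minus repressed, 24 h minus repressed, 24 h minus 4 h, and 24 h minus untreated. An exact two-sided test of 2 arrays against 2 cannot give a p below 0.333, and the model reaches lower values by pooling the spread over features and groups. The number of arrays limits the precision of every value.

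Of 46 gene lists fixed in advance, 38 had at least 5 tested members and were tested with camera at a correlation of 0.01, with Benjamini-Hochberg adjustment over 190 tests (38 lists in 5 comparisons). The tests were repeated with the correlation estimated from the residuals, and of the 123 calls made at 0.01, 0 held with an estimated correlation. That setting also uses only the 4 residual degrees of freedom, so its p-values do not show the effect of correlation within a list alone. Camera compares a list with all other features, most of them probes without a gene, and does not match them for signal. The lists cover the Myc network, growth and metabolism, the cell cycle, cell death and stress, B cell and immune programmes, lncRNAs, markers of other cell types and housekeeping genes. The list of snoRNA host lncRNAs had 0 members with a probe among the named genes. Some other lists were covered only in part. Tested were 8 of 74 mitochondrial ribosome genes, 19 of 66 ribosome biogenesis genes, 31 of 77 cytosolic ribosomal proteins and 10 of 49 replication-dependent histones. Statements on a list refer to its tested members. The lists of mitochondrial protein import, miRNA hosts, Myc-linked lncRNAs, well-known lncRNAs, and NK cell, fibroblast and erythroid markers had fewer than 5 tested members and are only described.

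Genes were named by a fixed rule. MYC is always named. In the first 3 comparisons the 6 coding genes with the largest rise and the 6 with the largest fall are named, with up to 4 lncRNAs per direction and up to 2 unnamed probes, among those past the threshold whose arrays did not overlap between the groups. In the last 2 comparisons the 4 largest rises and 4 largest falls are named. Size here is the estimated value, also where only a bound is known, so the order of dim genes is not known. Some genes that the rule picks are not reported here. Of each list up to 4 members with the smallest p in the direction most members took are named, and the member with the smallest p in the other direction. For a gene not well above background in the lower group the fold is a lower bound, printed as "at least". It is the mean of the higher group minus, for each array of the lower group, the higher of that array's lowest well-above-background signal and the gene's own signal.

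The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, scaling to 7 of the 10 RNA spike-in probes (which also carries any difference in input RNA, given in the labels only as a range), normexp background correction of the raw median signals with an offset of 50, the deposited log2 table, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, the replicate number as a block, an intensity trend in eBayes, fitting only the groups compared, a fold change of at least 2, fry in place of camera, and leaving out each array in turn. Counting custom probes as a class, the overlap with the 4 h calls, and spike-in scaling without the untreated array with the lowest spike-in signal were added after the data were seen. The method was tested on simulated data with the mean and spread of each feature as fitted. With 200 changed features of 30777, 2 of 67 planted changes of 0.5 on the log2 scale were recovered, 42 of 67 changes of 1 and 54 of 66 changes of 2, with 5 false calls. With 15388 changed features the recovered shares were 73.9%, 91.9% and 98.8%, and 2.38% of the calls were false. The planted changes went up about as often as down and were added to values already scaled. These simulations thus do not test the scaling between arrays, and their share of false calls does not cover errors of the scale. For the overlap of calls that share the repressed arrays, 100 simulations with no change in any group were run.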

Results

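The series profiled P493-6 B cells at different Myc levels to look for lncRNAs that depend on Myc. Myc is a transcription factor that drives cell growth and division. RNA of 8 samples was measured on arrays: 2 of untreated cells, 2 of cells with MYC repressed by tetracycline for 72 h, and 2 each of cells collected, as the labels are read here, 4 h and 24 h after tetracycline was removed. Between 31569 and 33549 of the 61657 RNA spots of each array (51.2% to 54.4%) were well above background. Replicates correlated across features at Pearson's r of 0.991 to 0.995, where features are not independent replicates. The first principal component held 64.2% of the variance and ordered the groups as untreated, 24 h, 4 h and repressed. The second held 17.5% and set the 4 h arrays (-67.2 and -69.9) apart from the other arrays. Changes are log2 differences ± SE of the limma model, with n = 2 arrays per group. For each gene given below as having risen or fallen, both arrays of 1 group lay above both arrays of the other.

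MYC signal, relative to the 75th percentile of each array, was 9.04 ± 0.24 (SD, n = 2) on the log2 scale in untreated cells and 4.64 ± 0.27 in repressed cells. MYC fell by 4.40 ± 0.17 with repression, a 21.2-fold change (adjusted p = 7.3e-06). The files do not say whether the probe detects the endogenous gene, the tetracycline-regulated gene or both. At 4 h after tetracycline was removed the signal was 9.59 ± 0.10, a rise of 4.96 ± 0.17 over repressed cells (adjusted p = 3.2e-05). At 24 h it was 9.12 ± 0.03, which differed from untreated cells by 0.08 ± 0.17 (adjusted p = 0.77) and from 4 h by -0.48 ± 0.17 (adjusted p = 0.064), neither past the threshold. The difference from 4 h did pass with normexp background correction, the filter on all arrays and the replicate block.

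**Figure D1:**
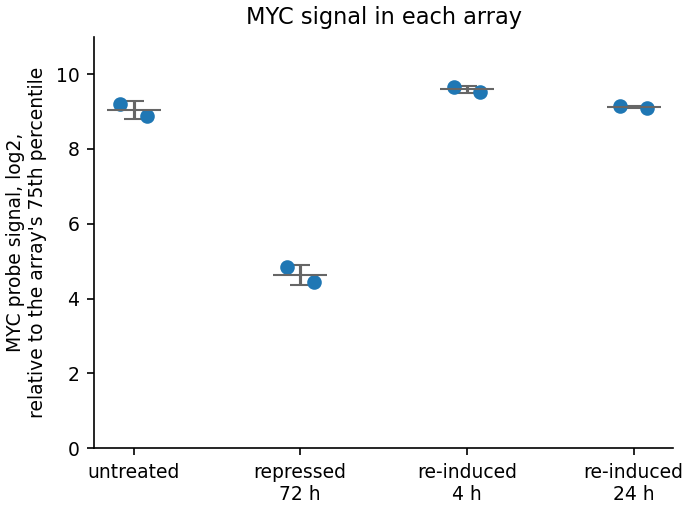
MYC probe signal (log2, relative to the 75th percentile of each array) in the 8 arrays by group; points are arrays, and bars are the group mean ± SD (n = 2). The repressed arrays lie at 4.83 and 4.45, and the lowest array of any other group lies at 8.87.

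The comparison of repressed with untreated cells asks which RNAs change when Myc is shut off. Immune genes were among those that rose. RSAD2, an antiviral protein induced by interferon, was at least 98.4-fold higher (adjusted p = 3.6e-06). CD1C, which presents lipid antigens, was at least 22.7-fold higher (adjusted p = 3.3e-06). The immune signalling adaptor FYB1, measured well above background on 1 of 2 untreated arrays, rose by 6.22 ± 0.17, and the interferon-induced genes OASL and XAF1 rose by 6.16 ± 0.21 and 5.86 ± 0.09. LIN28B, an RNA-binding protein that blocks let-7 maturation, was at least 163-fold lower (adjusted p = 4.3e-06), and the neuropeptide GAL fell by 7.51 ± 0.07. CTDSPL, a phosphatase, was at least 53-fold lower (adjusted p = 8.5e-06). The amino acid transporter SLC7A2 fell by 6.00 ± 0.07. The TNF receptor family member TNFRSF8 (CD30) was at -5.83 ± 0.09 and the kisspeptin receptor KISS1R at -5.56 ± 0.11.

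Genes of growth and biosynthesis fell together. Of 32 measured textbook Myc-activated genes, 31 fell and 1 did not pass (median -2.70), with adjusted p = 3.1e-14 by camera and adjusted p = 0.12 with an estimated correlation. They include the chaperonin HSPD1 (-3.03 ± 0.07), the prohibitin PHB1 (-2.93 ± 0.07) and lactate dehydrogenase LDHA (-3.13 ± 0.07). Of 23 textbook Myc-repressed genes 18 rose and 1 fell (adjusted p = 9.5e-05 by camera and adjusted p = 0.12 with an estimated correlation). The stress-response gene NDRG1 rose by 3.86 ± 0.10 and TXNIP, an inhibitor of thioredoxin and glucose uptake, by 3.78 ± 0.11. POLR1G, a subunit of RNA polymerase I, was at -3.84 ± 0.07 and the nucleolar helicase DDX21 at -2.79 ± 0.07. All 19 measured ribosome biogenesis genes fell (median -2.58), with adjusted p = 9.9e-11 by camera and adjusted p = 0.13 with an estimated correlation. The 12 genes of RNA polymerases I and III all fell as well (adjusted p = 8.4e-05; adjusted p = 0.14 with an estimated correlation). Of 31 cytosolic ribosomal proteins 29 fell, by less, with a median of -0.83 (adjusted p = 1.7e-08; adjusted p = 0.30 with an estimated correlation). Translation initiation and elongation factors fell in 32 of 34 cases and rose in 1 (adjusted p = 2.9e-11; adjusted p = 0.12 with an estimated correlation). Of the aminoacyl-tRNA synthetases, which charge tRNAs, 17 of 18 fell (adjusted p = 2.8e-08; adjusted p = 0.12 with an estimated correlation), and so did 19 of 21 chaperonin and folding genes (adjusted p = 8.9e-09; adjusted p = 0.14 with an estimated correlation).

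The purine enzyme PAICS was at -4.23 ± 0.09 and IMPDH2, which makes guanine nucleotides, at -2.83 ± 0.07. All 25 nucleotide synthesis genes fell (median -2.30), with adjusted p = 1.7e-12 by camera and adjusted p = 0.12 with an estimated correlation. Of 24 genes of serine, one-carbon and polyamine metabolism 21 fell and 1 rose (adjusted p = 1.3e-08; adjusted p = 0.12 with an estimated correlation). The mitochondrial folate enzyme MTHFD1L was at -4.60 ± 0.13 and PHGDH, the first enzyme of serine synthesis, at -3.53 ± 0.11. All 22 respiratory chain genes fell (median -1.24, adjusted p = 3.4e-09; adjusted p = 0.15 with an estimated correlation). So did 7 of 8 mitochondrial ribosomal proteins (adjusted p = 1.3e-04; adjusted p = 0.16 with an estimated correlation). All 4 mitochondrial import genes fell, too few to test as a list. Glycolysis genes fell in 14 of 19 cases and rose in 4, with glucose phosphate isomerase GPI at -2.70 ± 0.07 and by camera adjusted p = 3.2e-04 and adjusted p = 0.23 with an estimated correlation. The glucose transporter SLC2A3 was at least 8.56-fold higher (adjusted p = 4.0e-06). Cholesterol and fatty acid synthesis genes fell in 23 of 26 cases and rose in 2 (adjusted p = 4.1e-07; adjusted p = 0.20 with an estimated correlation). DHCR7, the last enzyme of cholesterol synthesis, fell by 3.21 ± 0.09.

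The mitotic kinases PLK1 (-3.02 ± 0.07) and BUB1 (-2.93 ± 0.06) fell. All 39 mitosis genes fell (median -2.32), with adjusted p = 1.6e-16 by camera and adjusted p = 0.12 with an estimated correlation. Of 38 DNA replication genes 37 fell (median -2.32, or -2.23 with a dim member at its bound, adjusted p = 2.9e-15; adjusted p = 0.12 with an estimated correlation). Among them were GINS2 (-3.82 ± 0.07) and MCM6 (-2.90 ± 0.08) of the replicative helicase. Of 21 genes that drive entry into S phase 19 fell and 1 rose (adjusted p = 3.6e-08; adjusted p = 0.12 with an estimated correlation). The kinase CDK4 fell by 2.52 ± 0.07 and the transcription factor E2F1 was at -2.48 ± 0.08, while the cyclin CCND3 rose by 0.65 ± 0.08 (0.12 with spike-in scaling, adjusted p = 0.52). Of 10 replication-dependent histone genes 8 fell and 1 rose (adjusted p = 0.0023; adjusted p = 0.39 with an estimated correlation). The rise was of H2BC12 (1.00 ± 0.08), a gene whose probes moved in opposite directions. Cell cycle inhibitors and quiescence genes rose in 16 of 22 cases and fell in 3 (adjusted p = 0.0014; adjusted p = 0.15 with an estimated correlation). The antiproliferative gene BTG2 was at 2.23 ± 0.11, YPEL5 at 2.99 ± 0.11 and the transcription factor FOXO3 at -1.59 ± 0.08. Of 19 p53 targets 14 rose and 0 fell, among them the death receptor FAS (1.92 ± 0.11) (adjusted p = 5.4e-04; adjusted p = 0.14 with an estimated correlation).

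Genes of the antiviral response rose, such as the enzyme OAS1 (4.81 ± 0.07), the RNA sensor RIGI (3.95 ± 0.07) and the signal transducer STAT2 (3.33 ± 0.07). All 25 measured type I interferon response genes rose (median 3.83), with adjusted p = 1.4e-12 by camera and adjusted p = 0.12 with an estimated correlation. Of 16 MHC class II genes 14 rose and 1 fell (median 2.84, adjusted p = 1.3e-06; adjusted p = 0.27 with an estimated correlation). The antigen-presenting chain HLA-DQA1 was at 3.70 ± 0.08, the class II transactivator CIITA at 3.12 ± 0.08 and the promoter-binding factor RFXAP at -0.98 ± 0.10. MHC class I and antigen processing genes rose in 14 of 16 cases and fell in 0, among them the immunoproteasome subunit PSMB9 (1.91 ± 0.06) (adjusted p = 4.0e-06; adjusted p = 0.18 with an estimated correlation). Of 26 B cell identity genes 25 rose, including the B cell receptor regulator CD72 (3.37 ± 0.10) and MS4A1 (CD20, 1.79 ± 0.07) (adjusted p = 7.0e-09; adjusted p = 0.15 with an estimated correlation). All 7 plasma cell genes fell, with the surface proteoglycan SDC1 at -2.95 ± 0.07 and the transcription factor XBP1 at -2.31 ± 0.09 (adjusted p = 0.0015; adjusted p = 0.14 with an estimated correlation). Adhesion molecules and chemokine receptors rose in 14 of 19 cases and fell in 1, with the integrin ITGB2 at 4.01 ± 0.08 (adjusted p = 1.1e-04; adjusted p = 0.15 with an estimated correlation). Among markers of other cell types, 2 of 7 of monocytes rose and 1 fell, with ITGAM at 5.16 ± 0.08 and CD68 at 4.23 ± 0.11. Of T cell markers 2 of 9 rose and 1 fell, with CD2 at 3.46 ± 0.11.

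In all, 1776 named genes rose and 2223 fell of 5323 tested. Adjusted over the list alone, the counts of the lists above were unchanged except for p53 targets (16 rose) and adhesion molecules (15 rose and 2 fell). Scaled to the spike-ins in place of the 75th percentile, the median change of all features moved from 0.08 to -0.45, and the calls among named genes became 974 higher and 2878 lower. Of that shift, 1 untreated array carried part, since without it the median was -0.30 and the calls were 1191 higher and 2659 lower. Apart from the T cell markers (0.14 and -0.39 with spike-in scaling), the median of each list described so far for this comparison kept its sign with spike-in scaling, with that of the interferon list at 3.30, that of the B cell identity list at 0.86 and that of the textbook Myc-repressed genes at 0.23. The median of the p53 targets was then 0.02, with 5 higher and 1 lower.

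**Figure D2:**
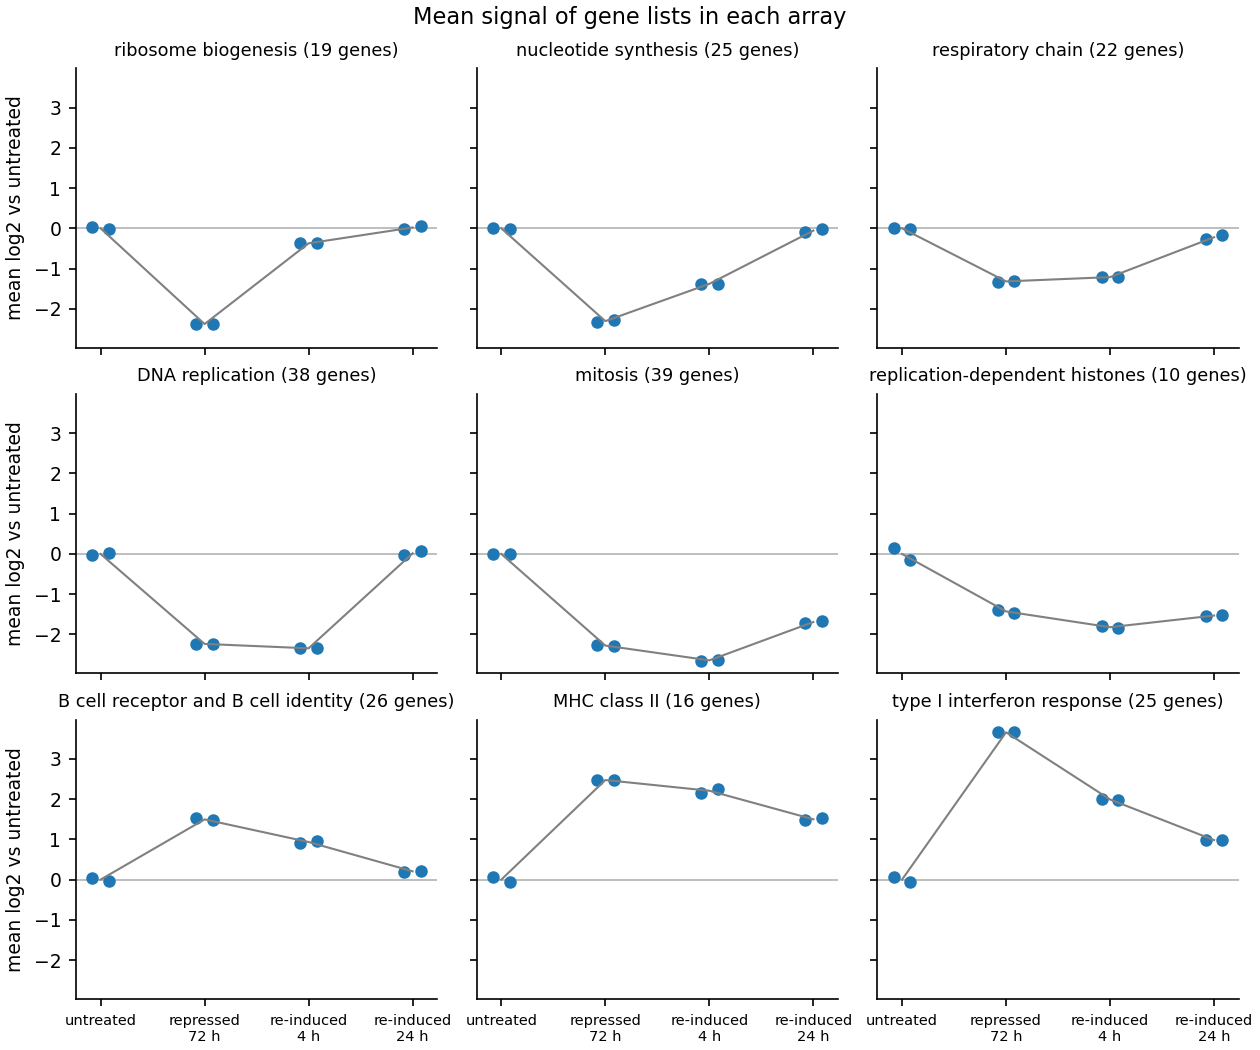
Mean log2 signal of 9 gene lists relative to the mean of the untreated arrays, by group; points are arrays (n = 2 per group), and lines join the group means. Mitosis genes were at a median of -1.69 against untreated cells at 24 h and DNA replication genes at -0.04; with spike-in scaling the medians were -1.91 and -0.25, and the small positive medians of ribosome biogenesis (0.02) and B cell identity (0.15) at 24 h became -0.19 and -0.06.

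The array names few lncRNAs. Of the 6 lncRNAs with a gene name, 5 rose with repression and 0 fell, a share of 83.3% against 75.1% of coding genes. With spike-in scaling the shares called were 33.3% and 72.4%. Against repressed cells, 33.3% of these lncRNAs and 55.1% of coding genes were called at 4 h, and 33.3% and 72.1% at 24 h. LINC00467 rose by 1.58 ± 0.07 (adjusted p = 1.0e-05), PVT1, a neighbour of MYC on its chromosome, by 0.92 ± 0.09 (adjusted p = 2.0e-04), the imprinted KCNQ1OT1 by 1.11 ± 0.32 (adjusted p = 0.024) and PCA3 by 0.62 ± 0.18 (adjusted p = 0.024). The call of PCA3 was lost under 7 of 12 alternatives (adjusted p up to 0.72) and that of KCNQ1OT1 under 4 (adjusted p up to 0.098). NBR2 rose by 0.31 ± 0.07 (adjusted p = 0.0078) but was at -0.22 with spike-in scaling, under which 1 of the 6 was called higher and 1 lower. Without the first repressed array 3 of the 6 rose. MIR155HG, the host of miR-155 and the 1 tested member of the list of miRNA hosts, did not pass (-0.20 ± 0.09, adjusted p = 0.088), but with spike-in scaling it was lower (-0.73, adjusted p = 0.0030). Both tested members of the list of Myc-linked lncRNAs (PVT1 and KCNQ1OT1) rose. Of the 4 well-known lncRNAs and other noncoding RNAs tested, LINC00467, RN7SK (1.05 ± 0.10), which holds back transcription elongation, and RMRP (0.60 ± 0.15) rose, and the telomerase RNA TERC fell (-0.47 ± 0.13). The call of TERC was lost under 5 of 12 alternatives (adjusted p up to 0.14) and that of RMRP under 2 (adjusted p up to 0.68).

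For the custom probes the files give no gene. Of the calls among them 66.0% were higher in repressed cells, against 44.3% of the calls among coding genes, but with spike-in scaling the shares were 21.9% and 25.2%. Spike-in scaling moves every feature of a comparison by the same amount, so it leaves the gap between the classes as it was. The median change was 0.17 for custom probes and -0.09 for coding genes, and -0.36 and -0.62 with spike-in scaling. Of 10880 tested, 3506 were higher and 1807 lower in repressed cells, but with spike-in scaling 1141 were higher and 4070 lower. In all, 48.8% of custom probes were called. In the 20% of features with the highest signal, 48.2% of custom probes were higher and 21.1% lower (median 0.24), against 31.1% and 55.4% of coding genes (median -0.41). CUST_51696_PI427622068 rose at least 50.0-fold (adjusted p = 3.2e-06) and CUST_5804_PI427622068 at least 30.3-fold (adjusted p = 2.2e-05). CUST_24535_PI427622068 fell at least 9.02-fold (adjusted p = 3.9e-06), and CUST_45781_PI427622068 was at -5.26 ± 0.18.

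**Figure D3:**
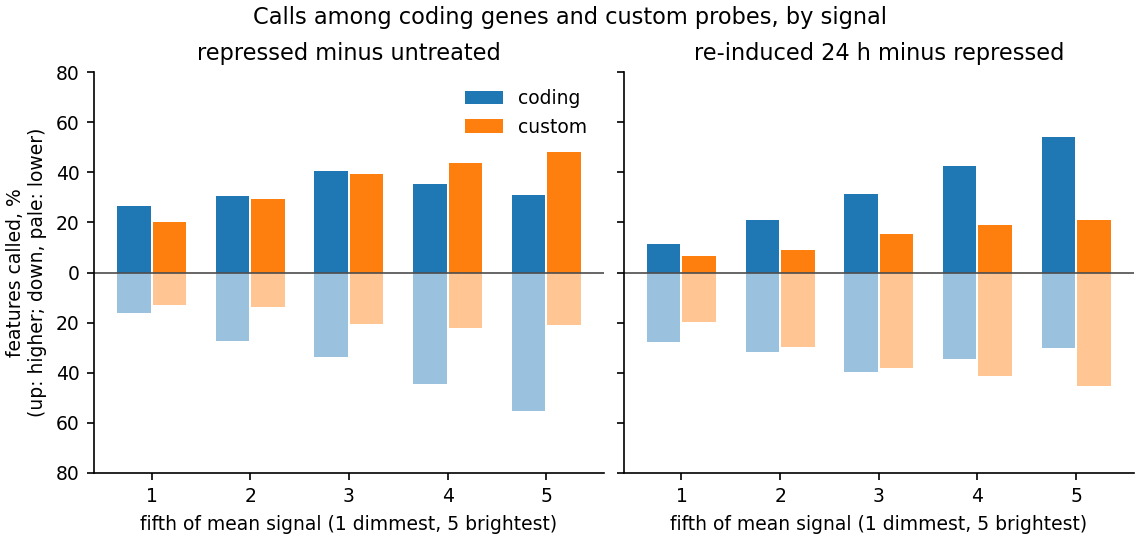
Percent of coding genes (blue) and custom probes (orange) called higher (bars up) and lower (pale bars down) in 5 equal bins of mean signal, for repressed minus untreated and 24 h minus repressed cells. In the brightest bin 48.2% of custom probes were higher in repressed cells and 45.4% lower at 24 h, a direction that holds for scaling to the 75th percentile, since with spike-in scaling 1141 custom probes of any signal were higher and 4070 lower in repressed cells and 1829 were higher and 1180 lower at 24 h.

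The comparison of cells 4 h after tetracycline was removed with repressed cells asks which RNAs change early when Myc returns. Effects of Myc, of tetracycline removal and of the fresh medium cannot be told apart in it. Besides MYC, the semaphorin receptor PLXNA1 (5.02 ± 0.13), the lactate transporter SLC16A1 (4.45 ± 0.19) and the cell cycle regulator RGCC (4.44 ± 0.09) rose. ANTXR1, an anthrax toxin receptor, rose at least 14.6-fold (adjusted p = 6.5e-04). IL12A, a subunit of interleukin 12, rose at least 4.71-fold (adjusted p = 3.4e-05). The protease inhibitor SERPINI1 was at least 4.67-fold lower (adjusted p = 2.3e-04), the phosphatase PTPRU at least 7.84-fold (adjusted p = 6.1e-05) and IL12B, another interleukin 12 subunit, at least 3.42-fold (adjusted p = 0.0014). The transcription factor MYBL1, well above background on 1 of 2 arrays at 4 h, fell by 3.84 ± 0.65. The adaptor DOK7 (-3.14 ± 0.21) and the Ras activator RASGRP1 (-3.11 ± 0.11) also fell.

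All 19 ribosome biogenesis genes rose at 4 h (median 1.92), led by POLR1G (3.74 ± 0.07) and NOLC1, a nucleolar scaffold (2.74 ± 0.08), with adjusted p = 4.5e-15 by camera and adjusted p = 0.12 with an estimated correlation. Of 32 textbook Myc-activated genes 27 rose and 2 fell (adjusted p = 5.6e-12; adjusted p = 0.13 with an estimated correlation). The textbook Myc-repressed genes fell in 9 of 23 cases and rose in 3 (adjusted p = 0.019; adjusted p = 0.15 with an estimated correlation). Genes of RNA polymerases I and III rose in 11 of 12 cases and fell in 1 (adjusted p = 1.0e-05; adjusted p = 0.13 with an estimated correlation). Translation factors rose in 26 of 34 cases (adjusted p = 2.3e-10; adjusted p = 0.12 with an estimated correlation). Chaperonin genes rose in 18 of 21 cases (adjusted p = 3.3e-09; adjusted p = 0.14 with an estimated correlation). Of 25 nucleotide synthesis genes 19 rose, with PAICS at 3.24 ± 0.09, and 4 fell (adjusted p = 1.5e-06; adjusted p = 0.15 with an estimated correlation). Cytosolic ribosomal proteins rose in 11 of 31 cases (median 0.22, adjusted p = 9.0e-05; adjusted p = 0.44 with an estimated correlation). Of 22 respiratory chain genes 5 rose, 3 fell and 14 did not pass (median 0.09). The list did not pass against other genes by camera (adjusted p = 0.17) but passed against no change by fry (adjusted p = 0.0081).

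Most cell cycle genes fell or did not pass at 4 h. Of 39 mitosis genes 23 fell and 3 rose (median -0.36, adjusted p = 2.1e-05; adjusted p = 0.14 with an estimated correlation). The kinetochore gene NDC80 was at -1.20 ± 0.07 and the mitotic transcription factor FOXM1 at -0.82 ± 0.09. Of 38 DNA replication genes 14 fell, such as the licensing factor CDT1 (-1.09 ± 0.12), and 6 rose, and the list did not pass (median -0.19, adjusted p = 0.12). Genes of S phase entry split 6 up and 7 down, with CDK4 at 1.35 ± 0.07 and E2F2 at -2.26 ± 0.08 (adjusted p = 0.73). Histone genes fell in 6 of 10 cases (adjusted p = 0.012; adjusted p = 0.47 with an estimated correlation). Cell cycle inhibitors and quiescence genes fell in 16 of 22 cases and rose in 1 (adjusted p = 5.4e-05; adjusted p = 0.12 with an estimated correlation). Among the falls were the cyclin-dependent kinase inhibitors CDKN2D (-2.51 ± 0.13) and CDKN1C (-1.91 ± 0.10).

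All 25 interferon response genes fell at 4 h (median -1.61), with XAF1 at -2.33 ± 0.09 (adjusted p = 1.2e-14; adjusted p = 0.12 with an estimated correlation). Of 16 MHC class II genes 4 fell, 1 rose and 11 did not pass (adjusted p = 0.027; adjusted p = 0.58 with an estimated correlation). B cell identity genes fell in 12 of 26 cases and rose in 1 (adjusted p = 3.5e-04; adjusted p = 0.30 with an estimated correlation). The B cell transcription factor EBF1 fell by 2.76 ± 0.09 and the activation marker CD83 rose by 1.86 ± 0.19. Of the named lncRNAs, MIR155HG rose by 1.61 ± 0.09 (adjusted p = 8.3e-05), LINC00467 fell by 0.72 ± 0.07 (adjusted p = 5.7e-04), and the other 4 did not pass. Of the custom probes 1192 were higher and 1400 lower (939 and 826 with spike-in scaling), with CUST_36791_PI427622068 at least 7.30-fold higher (adjusted p = 4.6e-04) and CUST_2721_PI427622068 at -3.80 ± 0.10. In all, 1467 named genes rose and 1466 fell, and with spike-in scaling 1158 rose and 948 fell. Adjusted over the list alone, 12 textbook Myc-repressed genes fell and 4 rose, 27 translation factors rose, 5 nucleotide synthesis genes fell and 7 genes of S phase entry rose. Counted the same way, 7 DNA replication genes rose and 15 fell, 24 mitosis genes fell, 17 quiescence genes fell and 2 rose, and 14 B cell identity genes fell.

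The comparison of cells 24 h after tetracycline was removed with repressed cells asks which RNAs follow Myc back over a day, with the same limit as at 4 h. Genes that had fallen were again high. LIN28B was at least 32.5-fold higher (adjusted p = 1.4e-05). GAL rose by 6.38 ± 0.07, KISS1R by 5.22 ± 0.11, SLC7A2 by 5.11 ± 0.07 and TNFRSF8 by 5.10 ± 0.09. The cortisol-inactivating enzyme HSD11B2, well above background on 1 of 2 repressed arrays, rose by 5.33 ± 0.23. The interferon-induced genes RSAD2 (-5.45 ± 0.18), IFI6 (-4.32 ± 0.12) and OASL (-4.26 ± 0.21) fell. INPP1, an inositol phosphatase, was at least 9.28-fold lower (adjusted p = 6.8e-06), PTPRU at least 9.39-fold (adjusted p = 1.2e-05) and IRAG1 at least 7.77-fold (adjusted p = 2.7e-05).

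Of 32 textbook Myc-activated genes 31 rose (median 2.61, adjusted p = 1.4e-16; adjusted p = 0.12 with an estimated correlation). Of 23 textbook Myc-repressed genes 20 fell and 1 rose (adjusted p = 8.3e-05; adjusted p = 0.12 with an estimated correlation). All members measured rose among ribosome biogenesis genes (19; median 2.52, adjusted p = 1.3e-12; adjusted p = 0.12 with an estimated correlation) and nucleotide synthesis genes (25; median 2.30, adjusted p = 1.9e-14; adjusted p = 0.12 with an estimated correlation). The same held for respiratory chain genes (22; median 1.14, adjusted p = 1.1e-09; adjusted p = 0.14 with an estimated correlation). The helicase genes GINS2 (3.67 ± 0.07) and MCM6 (3.42 ± 0.08) rose. All 38 DNA replication genes rose (median 2.30, or 2.23 with a dim member at its bound, adjusted p = 7.0e-18; adjusted p = 0.12 with an estimated correlation). So did 20 of 21 genes of S phase entry, with E2F1 at 2.99 ± 0.08 (adjusted p = 1.4e-09; adjusted p = 0.12 with an estimated correlation). Of 39 mitosis genes 26 rose and 3 fell, with a smaller median of 0.58 (adjusted p = 5.0e-06; adjusted p = 0.13 with an estimated correlation). The spindle checkpoint gene MAD2L1 rose by 2.73 ± 0.10 and the phosphatase CDC25B fell by 0.56 ± 0.12 (not past the threshold with spike-in scaling, adjusted p = 0.36). Histone genes split 3 up and 3 down (adjusted p = 0.85).

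All 25 interferon response genes fell (median -2.77, adjusted p = 3.1e-12; adjusted p = 0.12 with an estimated correlation), with STAT2 at -3.31 ± 0.07. MHC class II genes fell in 14 of 16 cases and rose in 1 (median -1.08, adjusted p = 9.4e-05; adjusted p = 0.34 with an estimated correlation). B cell identity genes fell in 25 of 26 cases and rose in 1 (adjusted p = 1.3e-08; adjusted p = 0.16 with an estimated correlation). CD72 was at -3.77 ± 0.10 and the kinase LYN at -1.60 ± 0.07. Beside them T cell markers fell in 6 of 9 cases and rose in 0, with CD2 at -2.11 ± 0.11 (median -0.91, adjusted p = 0.0091; adjusted p = 0.21 with an estimated correlation). Monocyte markers fell in 2 of 7 cases and rose in 0, with ITGAM at -3.03 ± 0.08 (adjusted p = 0.34). Of the plasma cell genes 3 rose and 2 fell of 7, with a median of -0.16 that was 0.16 with spike-in scaling and a mean of 0.27 (adjusted p = 0.76). Of the named lncRNAs, MIR155HG rose by 1.48 ± 0.09 (adjusted p = 4.2e-05), LINC00467 fell by 1.76 ± 0.07 (adjusted p = 1.2e-05) and the other 4 did not pass. Custom probes were higher in 1301 cases and lower in 3404, but 1829 were higher and 1180 lower with spike-in scaling. CUST_24531_PI427622068 was at least 34.3-fold higher (adjusted p = 5.0e-05) and CUST_5804_PI427622068 at least 31.9-fold lower (adjusted p = 7.0e-05). In all, 2086 named genes rose and 1751 fell, and with spike-in scaling, which moved the median of all features from -0.13 to 0.18, 2326 rose and 983 fell. Adjusted over the list alone, 27 mitosis genes rose and 4 fell, and the counts of the other lists just named were unchanged.

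Most genes that moved with repression moved back. Of 2223 named genes that fell with repression, 1909 (85.9%) rose by 24 h, where independent lists of these sizes would share 871. Of 1776 that rose, 1492 (84.0%) fell, where independent lists would share 584. Both comparisons use the same 2 repressed arrays, and no fit with a different repressed array for each was run, so part of the excess may come from the shared arrays. In simulations with no change in any group the covariance of the fold changes was -0.016, against -1.67 measured. Across genes, which are not independent replicates, r was -0.911 measured and -0.496 simulated. By 4 h, 1136 (51.1%) of the genes that fell had risen and 947 (53.3%) of those that rose had fallen. Independent lists would share 613 and 489. The covariance was -0.753 measured and -0.015 simulated, while r was -0.577 measured and -0.493 simulated. A shared group gives an r near the simulated value however small the spread is, so r does not show how much the shared arrays contribute. Another 302 genes fell both with repression and at 4 h and 152 rose both times, against 50 and 7 with 24 h in place of 4 h. Of the 1909 genes that fell and then rose by 24 h, 1101 had risen at 4 h, 731 rose between 4 h and 24 h and had not risen at 4 h, and 560 (29.3%) still differed from untreated cells. Of the 1492 that rose and then fell, 865 had fallen at 4 h, 523 fell between 4 h and 24 h and had not fallen at 4 h, and 666 (44.6%) still differed. The shares that still differed depend on the processing, since the calls of 24 h against untreated cells numbered 1800, but 1190 with spike-in scaling and 978 with no filter on dim probes.

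**Figure D4:**
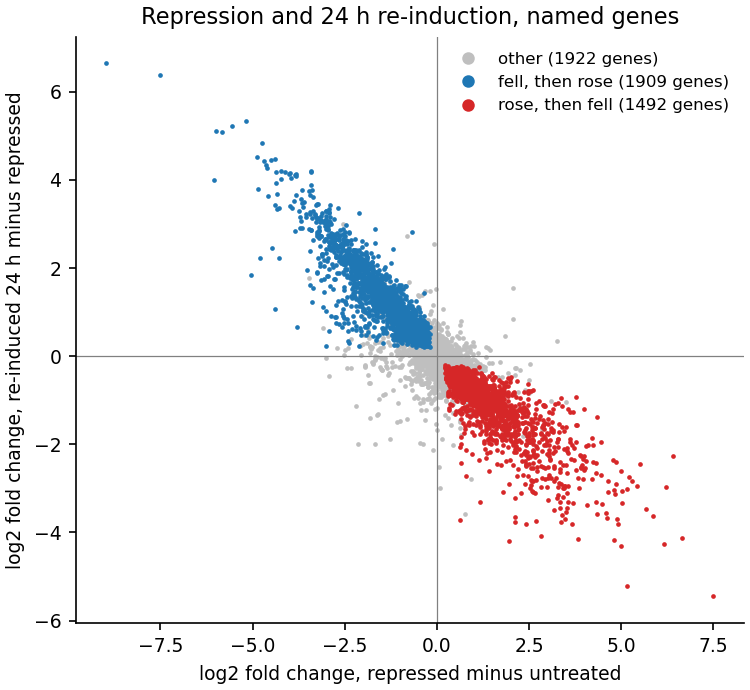
Log2 fold change of each named gene with repression (x axis, repressed minus untreated) and 24 h after tetracycline was removed (y axis, 24 h minus repressed); points are genes. Blue points are the 1909 genes that fell and then rose and red points the 1492 that rose and then fell, and the repressed arrays enter both axes.

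The comparison of 24 h with 4 h asks what changed late in re-induction. CDT1 (4.18 ± 0.12) and CDC45 (4.12 ± 0.11), which load and activate the replicative helicase, rose. CTDSPL rose at least 13.3-fold (adjusted p = 6.3e-05) and the glucose transporter SLC2A4 at least 10.8-fold (adjusted p = 0.0013). The kinase IRAK2 fell at least 10.9-fold (adjusted p = 8.8e-05) and the potassium channel subunit KCNS3 at least 8.33-fold (adjusted p = 9.5e-05). The growth factor receptor CSF1R fell at least 11-fold (adjusted p = 3.0e-04) and ANTXR1 at least 18.1-fold (adjusted p = 5.6e-04). Of 38 DNA replication genes 37 rose between 4 h and 24 h (median 2.31), including GMNN, which restrains licensing (2.98 ± 0.07), with adjusted p = 2.4e-23 by camera and adjusted p = 0.12 with an estimated correlation. Genes of S phase entry rose in 20 of 21 cases, such as the cyclin CCNE2 (3.04 ± 0.07) (adjusted p = 9.0e-13; adjusted p = 0.12 with an estimated correlation). Mitosis genes rose in 35 of 39 cases (median 0.94), with CDK1, the kinase that starts mitosis, at 1.61 ± 0.07 (adjusted p = 2.9e-14; adjusted p = 0.12 with an estimated correlation). Of 22 respiratory chain genes 21 rose, such as cytochrome c (CYCS, 1.18 ± 0.07) (adjusted p = 1.1e-11; adjusted p = 0.13 with an estimated correlation). Of 25 nucleotide synthesis genes 23 rose, with the thymidylate synthase TYMS at 2.70 ± 0.09 (adjusted p = 1.9e-13; adjusted p = 0.12 with an estimated correlation). Ribosome biogenesis genes rose further in 10 of 19 cases (median 0.26, adjusted p = 9.5e-05; adjusted p = 0.23 with an estimated correlation).

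B cell identity genes fell between 4 h and 24 h in 21 of 26 cases and rose in 2 (adjusted p = 7.7e-07; adjusted p = 0.19 with an estimated correlation). The coactivator POU2AF1 fell by 1.77 ± 0.09, and EBF1 rose by 1.50 ± 0.09. MHC class II genes fell in 14 of 16 cases and rose in 2 (adjusted p = 9.5e-05; adjusted p = 0.34 with an estimated correlation). Interferon response genes fell in 20 of 25 and rose in 2, with IFI6 at -3.49 ± 0.12 (adjusted p = 2.5e-06; adjusted p = 0.16 with an estimated correlation). Adhesion molecules fell in 14 of 19 cases and rose in 1, among them CD44 (-2.48 ± 0.07) (adjusted p = 3.4e-05; adjusted p = 0.14 with an estimated correlation). Beside these lists monocyte markers fell in 4 of 7 cases and rose in 0 (adjusted p = 0.036; adjusted p = 0.30 with an estimated correlation). T cell markers fell in 5 of 9 and rose in 0 (adjusted p = 0.029; adjusted p = 0.26 with an estimated correlation). Leaving out 4 h replicate 2 lost the call of the monocyte list, and leaving out 24 h replicate 1 that of the T cell list. In all, 1926 named genes rose and 1330 fell, and with spike-in scaling, which moved the median of all features from -0.08 to 0.19, 2183 rose and 676 fell. Adjusted over the list alone, 38 DNA replication genes, 37 mitosis genes and 22 respiratory chain genes rose, 23 B cell identity genes fell, and 3 interferon response genes rose and 21 fell.

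The comparison of 24 h with untreated cells asks how far the cells had come back. Most DNA replication and ribosome biogenesis genes did not differ from untreated cells past the threshold, while mitosis and histone genes were lower and MHC genes higher. All 39 mitosis genes were lower than in untreated cells (median -1.69, adjusted p = 4.4e-31; adjusted p = 0.12 with an estimated correlation). PLK1 was at -2.79 ± 0.07, BUB1 at -2.36 ± 0.06 and the spindle gene ASPM at -2.19 ± 0.06. All 10 histone genes were lower (median -1.57), with H1-5 at -1.98 ± 0.12 (adjusted p = 2.7e-09; adjusted p = 0.16 with an estimated correlation). Of 38 DNA replication genes 4 were higher, 2 lower and 32 did not pass (median -0.04, adjusted p = 0.97). Ribosome biogenesis genes did not pass in 16 of 19 cases (median 0.02, and -0.19 with spike-in scaling, adjusted p = 0.81). Textbook Myc-activated genes did not pass in 25 of 32 cases (adjusted p = 0.43). Cholesterol and fatty acid synthesis genes were lower in 20 of 26 cases and higher in 1 (adjusted p = 6.7e-10; adjusted p = 0.15 with an estimated correlation). Lanosterol synthase LSS was at -1.51 ± 0.08 and HMGCS1, an early enzyme of the pathway, at -1.32 ± 0.09. Cytosolic ribosomal proteins were lower in 10 of 31 cases (adjusted p = 1.7e-06; adjusted p = 0.36 with an estimated correlation). Genes of serine, one-carbon and polyamine metabolism were lower in 11 of 24 cases, with PHGDH at -1.58 ± 0.11 (adjusted p = 5.1e-04; adjusted p = 0.17 with an estimated correlation). All 7 plasma cell genes were lower, with CD38 at -1.89 ± 0.08 (adjusted p = 9.0e-07; adjusted p = 0.12 with an estimated correlation).

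MHC class II genes were still higher than in untreated cells in 13 of 16 cases (median 1.70), with HLA-DQA1 at 2.43 ± 0.08 (adjusted p = 2.0e-12; adjusted p = 0.15 with an estimated correlation). MHC class I genes were higher in 14 of 16 cases (adjusted p = 9.2e-08; adjusted p = 0.15 with an estimated correlation). Interferon response genes were higher in 19 of 25 and lower in 1 (median 1.03), with XAF1 at 2.23 ± 0.09 (adjusted p = 5.3e-10; adjusted p = 0.13 with an estimated correlation). The prostacyclin receptor PTGIR was higher at least 5.37-fold (adjusted p = 0.011, or 0.056 without 24 h replicate 2). FYB1, well above background on 1 of 2 untreated arrays, was at 3.26 ± 0.17. Lower were SERPINF1, an inhibitor of blood vessel growth (-4.12 ± 0.09), the nuclease DNASE1L3 (-3.68 ± 0.24), and the interleukin 21 receptor IL21R (-3.33 ± 0.13). The actin-binding CNN1 was lower at least 2.83-fold (adjusted p = 0.0012). Of the named lncRNAs PVT1 was higher by 1.15 ± 0.09 (adjusted p = 7.7e-04), MIR155HG by 1.28 ± 0.09 (adjusted p = 5.9e-04) and KCNQ1OT1 by 1.18 ± 0.32 (adjusted p = 0.043). The call of KCNQ1OT1 was lost under 7 of 12 alternatives, among them the fits without either 24 h array, with adjusted p up to 0.16. Of 9 T cell markers 4 were lower and 1 higher, CD2 (1.35 ± 0.11), with a median of -0.48, or -0.45 with dim members at their bounds (adjusted p = 0.027; adjusted p = 0.26 with an estimated correlation). The monocyte markers ITGAM (2.13 ± 0.08) and CD68 (1.83 ± 0.11) were higher, and the other 5 of 7 did not pass (adjusted p = 0.59 for the list). In all, 948 named genes were higher and 852 lower. Without untreated replicate 1 the calls numbered 1136, without 24 h replicate 1 983, and without 24 h replicate 2 963 (462 higher and 501 lower). With spike-in scaling, which moved the median of all features from -0.01 to -0.23, 292 were higher and 898 lower, or 603 and 712 without the untreated array with the lowest spike-in signal. Adjusted over the list alone, 15 ribosomal proteins, 22 cholesterol and fatty acid genes and 12 genes of serine, one-carbon and polyamine metabolism were lower (2 of the last higher). Counted the same way, 14 MHC class II genes and 20 interferon genes were higher, 1 MHC class I gene was lower, 3 DNA replication genes were higher and 1 lower, and 0 ribosome biogenesis genes passed.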

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

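The tests of explanations in this part were chosen only after the results had been seen.

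The spike-in RNAs are not part of the measured cell RNA and enter the report only as an alternative scale, and their signal relative to the 75th percentile of the array was higher in repressed than in untreated cells by 0.53 on the log2 scale. The 75th percentile lay at -2.82 ± 0.24 (SD, n = 2) relative to the spike-ins in untreated cells, -3.35 ± 0.01 in repressed cells, -3.31 ± 0.06 at 4 h and -3.04 ± 0.0036 at 24 h. Random differences between tubes in how much spike-in RNA was added would scatter the spike-in signal of replicates as widely as that of groups. An exact permutation test over the 105 ways to pair the 8 arrays gave p = 0.019 (the smallest possible is 0.00952). The tested value also holds the 75th percentile, which may pair the arrays by group on its own, so this test cannot decide. The log2 spike-in signal itself was 10.86 and 10.51 in the untreated arrays and 10.95 and 10.96 in the repressed arrays. Random differences between tubes thus stay open. Handling or labelling that differed by group cannot be told apart from the group, since each of the 4 groups lay in a slide column of its own. Less labelled RNA per amount of total RNA with Myc repressed also stays open, since the labels give the input RNA only as a range, and the 75th percentile relative to the spike-ins was 0.31 higher at 24 h than in repressed cells.

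The type I interferon genes rose with repression, by a median of 3.83 over 25 genes. Scaling to the 75th percentile would account for the rise only if it vanished with another scale. Spike-in scaling lowers each gene by 0.53 in this comparison by its construction, and the median was then 3.30. Probes near background in untreated cells would account for it only if brighter members moved less, and over the 24 members well above background on all 8 arrays the median was 3.76. The first value shows only that the rise was larger than the difference between these scales. The second argues against probes near background as the cause. Tetracycline or culture handling in place of the Myc level may also move these genes, and cannot be told apart from Myc here, since only repressed cells held tetracycline and the median was still 1.03 above untreated cells at 24 h after it was removed.

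Mitosis genes stayed below the untreated level at 24 h (median -1.69) while DNA replication genes did not. Scaling moves every gene of a comparison by the same amount, so it cannot account for the gap between the lists. With spike-in scaling the median of the mitosis list was -1.91. Fewer cells in cycle at 24 h than in untreated cells would be expected to lower both lists, and the DNA replication list lay at -0.038. Replication-dependent histones, which are made in S phase, lay at -1.57, as fewer cells in cycle would give. These lists disagree, so this cause stays open. Cells that re-entered the cycle but had mostly not reached mitosis are another candidate explanation that stays open, since the low histone values leave the phase undecided and no cell counts or cycle profiles were analysed here.

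Some genes moved in opposite directions at 4 h and at 24 h against the same repressed arrays, with the difference between the times past the threshold of the limma test. There were 326 such named genes among those well above background on all repressed and re-induced arrays, 210 lower at 4 h and higher at 24 h and 116 the other way. Of these, 21 moved at least 2-fold at both times, 11 lower and then higher and 10 higher and then lower. The median of the mitosis list was -0.36 at 4 h and 0.58 at 24 h, and its median difference between the times was 0.94. CDT1, which licenses replication origins, was 4.18 ± 0.12 higher at 24 h than at 4 h (-1.09 ± 0.12 at 4 h and 3.08 ± 0.12 at 24 h against repressed cells). The S phase transcription factor E2F2 was 3.30 ± 0.08 higher (-2.26 ± 0.08 and 1.05 ± 0.08). ORC6, a subunit of the origin recognition complex, was 2.18 ± 0.12 higher (-1.02 ± 0.12 and 1.15 ± 0.12), and RBL1, a relative of the retinoblastoma protein, was 2.75 ± 0.12 higher (-1.21 ± 0.12 and 1.53 ± 0.12). The repressed arrays enter both changes of each gene, but the difference between the times does not use them.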

How the results depend on the processing

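Spike-in scaling without the untreated array with the lowest spike-in signal, the counts of custom probes and the overlap at 4 h were chosen after seeing the data, and the other alternatives had been fixed. Blocks for the array's row or column and for slide or scan were not run, since row and column match replicate number and group and there was 1 slide and 1 scan. In fits without 1 array, the lone array of its group is assumed to vary like the other groups.

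The fall of MYC with repression was between -4.93 and -4.02 under the alternatives other than leaving out an array and between -4.60 and -4.21 without 1 array, past the threshold each time. The count of named genes changed by repression ranged from 3665 to 3783 without 1 array, at 4 h from 2296 to 2453, at 24 h from 3380 to 3421, and between 4 h and 24 h from 2593 to 2823. Counting only changes of at least 2-fold lowers any count by its construction, to 2274, 974, 1870, 1137 and 445 named genes in the 5 comparisons. It gave 2 lncRNAs with repression and 1 at 4 h, and 2284, 814 and 1595 custom probes with repression, at 4 h and at 24 h. With the replicate block, 4000 genes were called with repression, against 3999 without it, and residuals of arrays with the same replicate number correlated at r from -0.005 to 0.073 across features.

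The comparison of 24 h with untreated cells changed under more alternatives than the other gene counts. Its 1800 genes became 1190 with spike-in scaling, 978 with no filter on dim probes and 1163 with only the 2 groups' arrays in the fit, which leaves fewer degrees of freedom. Leaving out an array gave 963 to 1322 genes (1136 without untreated replicate 1, 983 without 24 h replicate 1 and 963 without 24 h replicate 2). For spike-in scaling and the filter the cause was not tested.

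Of the lncRNAs, 5 rose with repression, but 2 passed with spike-in scaling and 3 with no filter on dim probes, and 3 to 4 when an array was left out (3 without repressed replicate 1). NBR2 reversed to -0.22 with spike-in scaling, which lowers each gene by 0.53 in this comparison by its construction. The share of changed lncRNAs was 83.3%, and 78.9% with NR accessions in place of RefSeq gene types. Of the 19 features with NR accessions 10 rose and 5 fell, so that class did not move in 1 direction only. The custom probes called at 24 h numbered 4705 and 3009 with spike-in scaling, and the cause was not tested. The overlap of genes that changed with repression and back by 24 h (3401) was 3029 to 3276 without 1 array, and that at 4 h (2083) was 1641 to 2003.

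Camera called 123 list results, while fits without 1 array called 122 to 126, which does not say how many were the same. With an estimated correlation it called 0. That setting allows for the correlation of genes within a list, but it also tests with only the 4 residual degrees of freedom. Correlation within a list is thus not the only reason for the loss of calls. For the textbook Myc-repressed genes with repression the estimated correlation was -0.013, yet the camera p went from 3.7e-05 to 0.010. For the genes named in the text, 2212 alternative values kept direction and side of the threshold, 40 fell short of it, 5 passed it where the reported value had not, and 1 reversed. The 40 belong to 13 results: CCND3, CD14, CD3D, GZMB, H2BC12, KCNQ1OT1, PCA3, PVT1, RMRP and TERC with repression, CDC25B at 24 h, and KCNQ1OT1 and PTGIR against untreated cells. Leaving out an array lost the call of CD14 (untreated replicate 2, repressed replicate 2), GZMB (untreated replicate 1, either repressed array), PCA3 (either untreated array, repressed replicate 1), TERC (untreated replicate 1, repressed replicate 2), RMRP (repressed replicate 1) and KCNQ1OT1 (either repressed array). Their adjusted p then lay between 0.057 and 0.11. KCNQ1OT1 at 24 h against untreated cells lost its call without untreated replicate 2 or either 24 h array, with adjusted p up to 0.16, and PTGIR without 24 h replicate 2 (adjusted p = 0.056). The fall of MYC from 4 h to 24 h passed with normexp background correction (adjusted p = 0.032), the filter on all arrays (0.042) and the replicate block (0.024). Of the list results in the text, 1279 alternative values kept direction and side, 97 fell short (81 of them with an estimated correlation) and 20 passed where they had not, 13 of these with fry. Leaving out an array lost the camera call of MHC class II at 4 h (repressed replicate 1 or 4 h replicate 1), of NF-kB targets with repression (untreated replicate 2), of monocyte and T cell markers from 4 h to 24 h (4 h replicate 2 and 24 h replicate 1, respectively) and of T cell markers against untreated cells (untreated replicate 1), with adjusted p of 0.050 to 0.13. Signal over background limits what can be said of dim probes, since 51.2% to 54.4% of spots were well above background.

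Over the genes that the naming rule picks, other than those not reported here, 10339 alternative values kept direction and side of the threshold, 500 fell short (in 144 results), 19 passed newly and 6 reversed. Besides NBR2, the reversals were of EIF4A2 (-0.00058) and KRT8 (-0.037) with repression under the same lowering by spike-in scaling, of FDXR at 24 h under quantile normalization (-0.033) and with the deposited table (-0.0038), and of MXI1 from 4 h to 24 h with the mean of its probes (-0.17), which were called in opposite directions there. Over all lists tested, 1 result reversed, that of EBNA2 and latent virus genes at 24 h, with a median of -0.53 and a camera test that did not pass, while fry called the list higher. The mean of this list relative to untreated cells was -0.37 and -0.51 on the repressed arrays and 0.16 and 0.10 on the 24 h arrays, so its mean and median moved in opposite directions. For FDXR and the EBNA2 list the cause was not tested.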

Other observations

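Several lists and cell-type markers with fewer or mixed changes are given here. Of 18 genes of the Myc network 6 rose and 7 fell with repression, with RUVBL2, a Myc cofactor, at -2.84 ± 0.09 and the antagonist MXD1 at 1.23 ± 0.08. The median was -0.09 (-0.62 with spike-in scaling, and positive with quantile normalization), the mean -0.75, and the list did not pass (camera, adjusted p = 0.35). Lysosome and autophagy genes rose in 21 of 36 cases and fell in 5, with the protease TPP1 at 2.39 ± 0.13 (median 0.49, -0.04 with spike-in scaling, adjusted p = 0.0054; adjusted p = 0.40 with an estimated correlation). Of 21 genes of the unfolded protein and integrated stress response 13 fell and 2 rose (adjusted p = 0.0051; adjusted p = 0.39 with an estimated correlation). The stress regulators ATF4 and DDIT3 were at -1.40 ± 0.07 and 1.52 ± 0.12. At 4 h 10 genes of this list rose and 3 fell (adjusted p = 0.0062; adjusted p = 0.39 with an estimated correlation), or 12 and 4 adjusted over the list alone. Heat shock genes fell in 4 of 10 cases and rose in 1, the chaperone HSPA6 (3.38 ± 0.08), and did not pass as a list (adjusted p = 0.22). At 24 h 8 of them were higher than in untreated cells and 1 lower (median 0.57, adjusted p = 0.0025; adjusted p = 0.30 with an estimated correlation). Of 16 BCL2 family genes 10 rose and 5 fell, with the death-promoting HRK at 3.72 ± 0.07 and BCL2L11 (BIM) at -1.71 ± 0.07 (median 0.35, -0.18 with spike-in scaling, adjusted p = 0.30).

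Targets of NF-kB rose with repression in 16 of 25 cases and fell in 3, with the cytokines TNF at 3.98 ± 0.09 and CCL4 at -1.48 ± 0.30 (median 0.49, -0.04 with spike-in scaling, adjusted p = 0.010; adjusted p = 0.40 with an estimated correlation). At 24 h 14 of these genes were still higher than in untreated cells and 2 lower (adjusted p = 6.5e-05; adjusted p = 0.25 with an estimated correlation), or 14 and 3 adjusted over the list alone. Germinal centre genes split 4 up and 2 down of 7, with the transcription regulator LMO2 at 5.50 ± 0.09 (median 1.00, or 0.73 with a dim member at its bound, adjusted p = 0.21). Genes of the EBNA2 and latent Epstein-Barr virus response split 5 up and 5 down of 12, among them the cytokine subunit EBI3 (1.94 ± 0.10), with a median of 0.10 (-0.43 with spike-in scaling) and a mean of -0.44 (adjusted p = 0.98). Housekeeping genes fell in 10 of 15 cases and rose in 4, with GAPDH at -1.72 ± 0.08, HPRT1 at -2.27 ± 0.07 and B2M at 1.37 ± 0.08 (median -0.83, adjusted p = 0.023; adjusted p = 0.40 with an estimated correlation).

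No list of markers of other cell types passed camera with repression. Of 9 T cell markers 2 rose and 1 fell (median 0.14, 0 with a dim member at its bound and -0.39 with spike-in scaling, adjusted p = 0.65), where CD3D was at 0.86 ± 0.15 (0.33 with spike-in scaling, adjusted p = 0.064) and LCK at -0.56 ± 0.12. Of 7 monocyte markers 2 rose and 1 fell, with CD14 at -0.37 ± 0.10 (median -0.05, or -0.01 with dim members at their bounds, and mean 1.03, with the median -0.58 under spike-in scaling and positive with normexp background correction, adjusted p = 0.62). The call of CD14 was lost under 4 of 12 alternatives, among them the fits without untreated replicate 2 or repressed replicate 2, with adjusted p up to 0.16. Of 6 epithelial markers 1 rose and 1 fell, EPCAM by 3.19 ± 0.17 (median 0.20 and mean -0.23, -0.33 for the median with spike-in scaling, adjusted p = 0.87). Among markers too few to test as lists, the smooth muscle actin ACTA2 (3.19 ± 0.15) and PDGFRB (2.08 ± 0.06) of fibroblasts rose, and the granzyme GZMB (-0.29 ± 0.07) of NK cells and SLC4A1 (-1.49 ± 0.14) of erythroid cells fell. The call of GZMB was lost under 5 of 12 alternatives, among them the fits without untreated replicate 1 or either repressed array, with adjusted p up to 0.37.

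Of the named genes called, 159, 96, 130, 113 and 70 in the 5 comparisons, in the order of the processing section, were not well above background in the lower group, so that their folds are lower bounds. Of 411 named genes with several probes, 17, 6, 9, 14 and 4 had probes called in opposite directions in these comparisons, and of the genes named in this text H2BC12 was 1 of the 17 and MXI1 1 of the 14.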
